A study of Homo sapiens with 8 samples.

How the data were processed

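Total RNA of A549 cells, an established human lung adenocarcinoma line, was measured on an Illumina HumanRef-8 v3 expression BeadChip, on which each probe is a bead-bound oligonucleotide read as a fluorescence intensity. All 8 arrays are of cells carrying a short hairpin RNA against GLP, the histone H3 lysine 9 methyltransferase encoded by EHMT1. Per the labels, 4 arrays were taken at 0 h and 4 at 24 h of 100 nM dexamethasone, a synthetic ligand of the glucocorticoid receptor, after growth in phenol red-free medium with hormone-depleted serum. Whether the 0 h cells received vehicle is not stated in the sources used here. The study's design also names cells without this hairpin, which are not analysed here.

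The deposited table of unprocessed values gives, per the file headers, a mean intensity over beads for each probe and array, on a linear scale and with no background subtracted as far as the values show. The same deposited table gives a detection p-value for each probe and array, which is the share of the array's negative control beads at least as bright. The authors' normalized table holds log2 values for 22011 of the 25204 rows, and the submitters' processing notes name limma without a version or function. Column by column, the authors' log2 values correlated with the log2 intensity of the same array at r = 0.987 to 0.998 across probes. For 0 h replicate 1 they correlated more with the intensity of another array (r = 0.990) than with its own (r = 0.987). That array had the lowest median intensity. Its authors' values correlated at r = 0.998 with its own values as normalized below. The medians of the authors' values lay between 6.95 and 6.97. The steps of their normalization, and whether a background was removed, are not given in the sources used here. Scanner software is likewise not given there.

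Intensities were background-corrected with the nec function of limma 3.58.1 (R 4.3.3), which takes the background from the detection p-values, with an offset of 16. The 22011 probes of the authors' table were then quantile normalized and put on the log2 scale. A probe was tested where its detection p-value was under 0.05 on at least 4 of the 8 arrays, which left 14533 probes. lmFit and eBayes compared 24 h with 0 h, 4 arrays each, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Counts of genes use the brightest tested probe of each gene over all 8 arrays, which gave 10964 genes. Of the 22011 probes, 19759 have 1 gene symbol in the platform annotation, none has several and 2252 have none. For 19741 of them the symbol was updated or kept through its Entrez identifier in a RefSeq gene table of assembly GRCh38.p14, and 18 symbols stayed as annotated. No coordinates are given because the array tables name no genome build. Members of near-identical families (the MT1 genes, SAA1 and SAA2, CIDEC and its pseudogene) may share signal on a probe.

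A gene not detected on any array of one time has only a bound there. Its fold is then given as "at least", from the bright group's mean against the mean, per array, of the higher of the lowest detected signal and the probe's own signal. Replacing fitted changes by these bounds altered no list median. Changes are given as log2 differences with the standard error of the limma fit, and levels as mean ± SD over 4 arrays.

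A total of 22 gene lists and 4 lists of cell type markers were fixed before the data were examined, as were the normalization, the filter, the threshold, the tests and the rule for named genes. That rule takes the 12 largest rises and the 12 largest falls among called genes whose arrays do not overlap between the times, up to 4 members of each list with the smallest p, any list member given as a value for one that did not pass, and EHMT1, EHMT2 and NR3C1. Lists of at least 5 tested genes were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's own genes move one way on balance, and does not compare them with other genes. The lists share members, so their tests are not independent. Of called genes, MT1X and MT2A (metallothioneins) and SERPINA3 and THBD (coagulation) are also in the glucocorticoid-induced list. So are TSC22D3 and SGK1 (ion transport) and CIDEC, ANGPTL4, PDK4 and IRS2 (lipid). Also shared with it are CDKN1C (kinase inhibitors), PER1 (clock) and DUSP1 and ERRFI1 (MAP kinase feedback).

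A set of 609 rows outside the authors' table was taken as negative controls, because their intensities mark the steps of the detection p-value on at least 7 of the 8 arrays. The other 2584 rows outside that table could not be told from control rows by name and were left out of the main test. Both choices were made after the files had been inspected and before the comparison was run. Numbers of called genes under several normalizations had been looked at before the final computation, and the main setting stayed as fixed.

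The arrays lie on 2 slides, 4 on each, at the positions lettered B, D, F and H in the file headers. Slide 1 holds replicates 1 and 2 of both times and slide 2 holds replicates 3 and 4. Along each slide the 0 h and 24 h arrays alternate, and no position was used for both times. The labels do not say that replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. Replicate numbers come from the sample titles. Across probes, the deviations from the group means of same-numbered arrays correlated at r = 0.46, 0.46, 0.37 and 0.46, against -0.54 to 0.19 for other pairs of opposite time, and all 8 arrays correlated best with their own number. These correlations were seen together with the number of genes called under the block, but the rule applied, every same-numbered correlation above 0.1, had been set beforehand. The numbers were therefore treated as pairing the samples. Same-numbered arrays, however, also follow each other among the analysed positions of their slide (B and D, or F and H). The main fit, fixed beforehand, has no block. Values with the replicate number as a block are given where they change a call or move a count by more than 1.5 times.

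Median intensity per array ran from 137 to 273, the median of the negative control rows from 85.0 to 121, and the share of probes detected from 63.1% to 67.2%. The number of arrays limits the precision. No arrays were identical. Replicates of one time correlated at r = 0.974 to 0.991 across probes and arrays of different times at 0.957 to 0.980. After the comparison had first been run, the fit was checked on simulated data made from the means and spreads of the 14533 tested probes, without the pairing. It recovered 22.4% of 67 probes changed 1.5-fold, 68.7% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, with 2 false calls. In the data 1435 probes were called, far more than were changed here. Recovery depends on the share of changed probes, so these rates may differ from those in the data. Camera on simulated values for 10964 genes found the 1 shifted list and called 0 of 20 unshifted ones. The simulated genes varied independently, so this could not show false calls for lists whose members vary together. Estimated correlations in the data were 0.588 for the cell cycle list and 0.815 for metallothioneins.

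A total of 23 alternatives were planned, among them other background corrections and normalizations, the authors' values, other filters, the mean over probes, another variance model, blocks, each slide alone and leaving out each array. Another 2 alternatives, 5 gene lists and the comparison of the slides were added after the data had been seen.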

Results

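Expression was profiled in A549 lung adenocarcinoma cells carrying a hairpin against GLP (EHMT1), at 0 h and after 24 h of 100 nM dexamethasone, with 4 arrays at each time. The comparison asks which genes differ after hormone in cells carrying a hairpin against this coregulator of the glucocorticoid receptor. No 24 h array without dexamethasone was analysed, so 24 h in culture cannot be told apart from the hormone. Between 13897 and 14797 of the 22011 probes were detected per array, and median intensity ran from 137 to 273. The first principal component held 45.6% of the variance and parted the times, and the next held 22.1% and parted the slides.

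EHMT1, the gene the hairpin targets, lay near background. Its 1 probe read log2 5.46, 5.55, 5.11 and 5.36 in replicates 1 to 4 at 0 h, and 5.75, 5.69, 5.66 and 5.78 at 24 h. It was detected on 1 of 4 arrays at 0 h and on 4 of 4 at 24 h, and the difference of 0.35 ± 0.13 (SE) did not pass (adjusted p = 0.135, limma). Depletion cannot be read from these values, since each array is of hairpin-bearing cells. EHMT2, the partner methyltransferase G9a, differed by -0.30 ± 0.12 (adjusted p = 0.178), and NR3C1, the glucocorticoid receptor, by -0.06 ± 0.16 (adjusted p = 0.877).

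After 24 h of dexamethasone, most known glucocorticoid-induced genes were higher and most tested inflammatory genes lower, and these 2 lists passed camera with its preset and with an estimated correlation. Most metallothioneins and coagulation and acute phase genes were higher and most cell cycle genes lower. These 3 lists passed camera only with the preset correlation (adjusted p = 0.162, 0.168 and 0.159 with an estimated one). They also passed fry, which does not compare them with other genes (adjusted p = 0.00314, 0.00298 and 0.00314). SERPINA3, an acute phase protease inhibitor, had the largest rise among genes detected at both times, 45.3-fold, from log2 8.29 ± 0.53 to 13.79 ± 0.46 (SD, n = 4 arrays each, limma adjusted p = 1.72e-06). HSD11B1, the enzyme that regenerates active cortisol, rose at least 20.9-fold, and SCNN1G, the gamma subunit of the epithelial sodium channel, at least 13.7-fold, both from a level not detected at 0 h. The largest estimated fall was that of AMHR2, the receptor of anti-Müllerian hormone, detected on 1 of 4 arrays at 24 h, with a log2 change of -2.76 ± 0.39 (SE) (adjusted p = 0.00146).

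In all, 1113 of 10964 genes passed the limma test at an adjusted p of 0.05, with 522 higher and 591 lower at 24 h. With the replicate number as a block the counts were 888 higher and 1002 lower. A change of at least 1.5-fold was estimated for 450 of the higher and 511 of the lower genes, and of at least 4-fold for 61 and 11. The arrays of the times did not overlap for 1904 genes (17.4%, where chance gives 2.86%), and 1075 of these were called. Among called genes, 24 were detected on no array at 0 h and 11 on none at 24 h. Probes of 1 gene were never called in opposite directions, but for 157 genes some probes were called and others not.

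**Figure D1:**
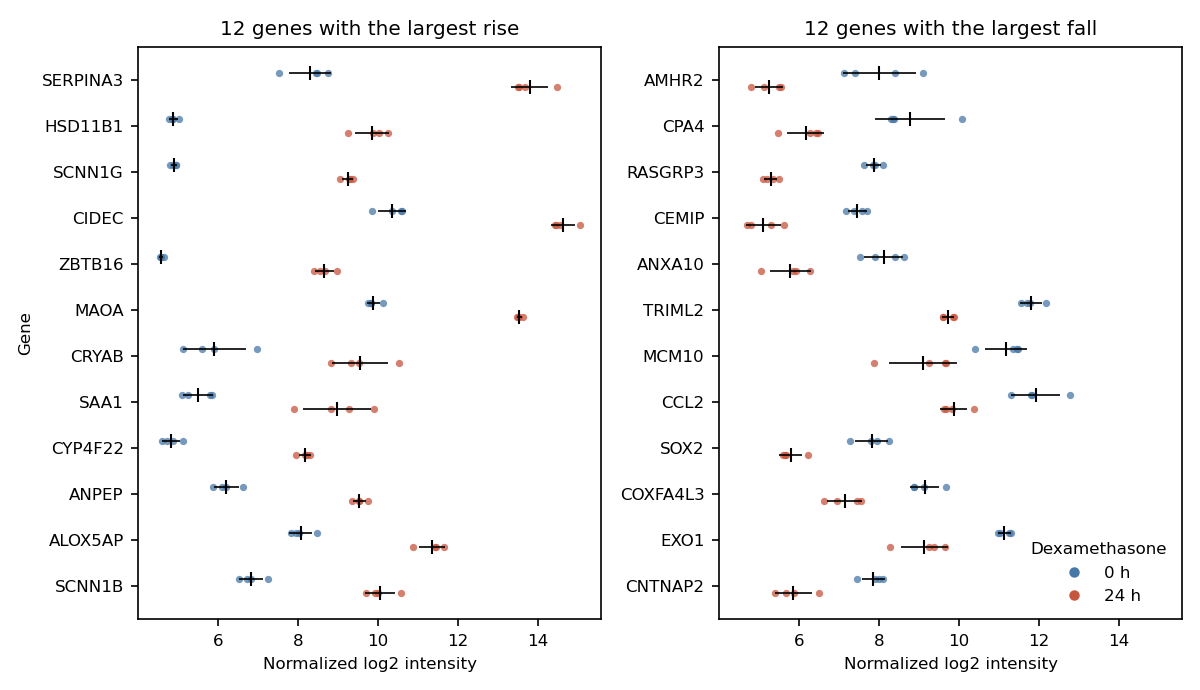
Normalized log2 intensity (x axis) of the 12 genes with the largest rise and the 12 with the largest fall at 24 h of dexamethasone. Points are arrays, ticks are means and bars are SD over the 4 arrays of each time, 0 h in blue and 24 h in red. The 4 arrays of 1 time lie on 1 side of the 4 of the other for each gene, by the rule that chose them.

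Among the 12 largest rises, CIDEC, a lipid droplet protein, rose 19.4-fold, MAOA, which oxidises monoamines, 12.6-fold, and ZBTB16, a zinc finger transcription factor, at least 9.11-fold. CRYAB, a small heat shock protein, rose by 3.65 ± 0.41 (SE) on the log2 scale, ANPEP, the aminopeptidase N, by 3.33 ± 0.17 and ALOX5AP, a protein needed for leukotriene synthesis, by 3.29 ± 0.20. CYP4F22, a fatty acid hydroxylase, rose at least 6.48-fold, and SCNN1B, the beta subunit of the sodium channel, 9.34-fold. Adjusted p for these genes ran from 1.38e-07 (MAOA and ZBTB16) to 0.000427 (CRYAB). SAA1, an acute phase protein detected on 2 of 4 arrays at 0 h, rose by 3.49 ± 0.37 on its brightest probe, while a dimmer SAA1 probe differed by 0.37 and did not pass (adjusted p = 0.273). CRYAB was detected on 3 of 4 arrays at 0 h.

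Among the 12 largest falls were CPA4, a carboxypeptidase, at -2.62 ± 0.39, and RASGRP3, an activator of Ras, at -2.58 ± 0.14 (log2 change ± SE). CEMIP, which binds hyaluronan, changed by -2.36 ± 0.22, and ANXA10, an annexin, by -2.34 ± 0.29. MCM10, which acts in DNA replication, changed by -2.07 ± 0.39, and EXO1, a DNA repair exonuclease, was 4.01-fold lower. CCL2, which attracts monocytes, changed by -2.05 ± 0.29 and SOX2, a transcription factor of stem and progenitor cells, by -2.03 ± 0.22. TRIML2 changed by -2.08 ± 0.16, COXFA4L3 was 4.01-fold lower, and CNTNAP2, a cell adhesion protein, went from log2 7.86 ± 0.29 to 5.86 ± 0.46 (SD, n = 4 arrays each). RASGRP3 and CEMIP were detected on 1 of 4 arrays at 24 h, and ANXA10 and CNTNAP2 on 3 of 4. Adjusted p for these falls ran from 3.13e-06 (RASGRP3) to 0.00753 (MCM10).

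**Figure D2:**
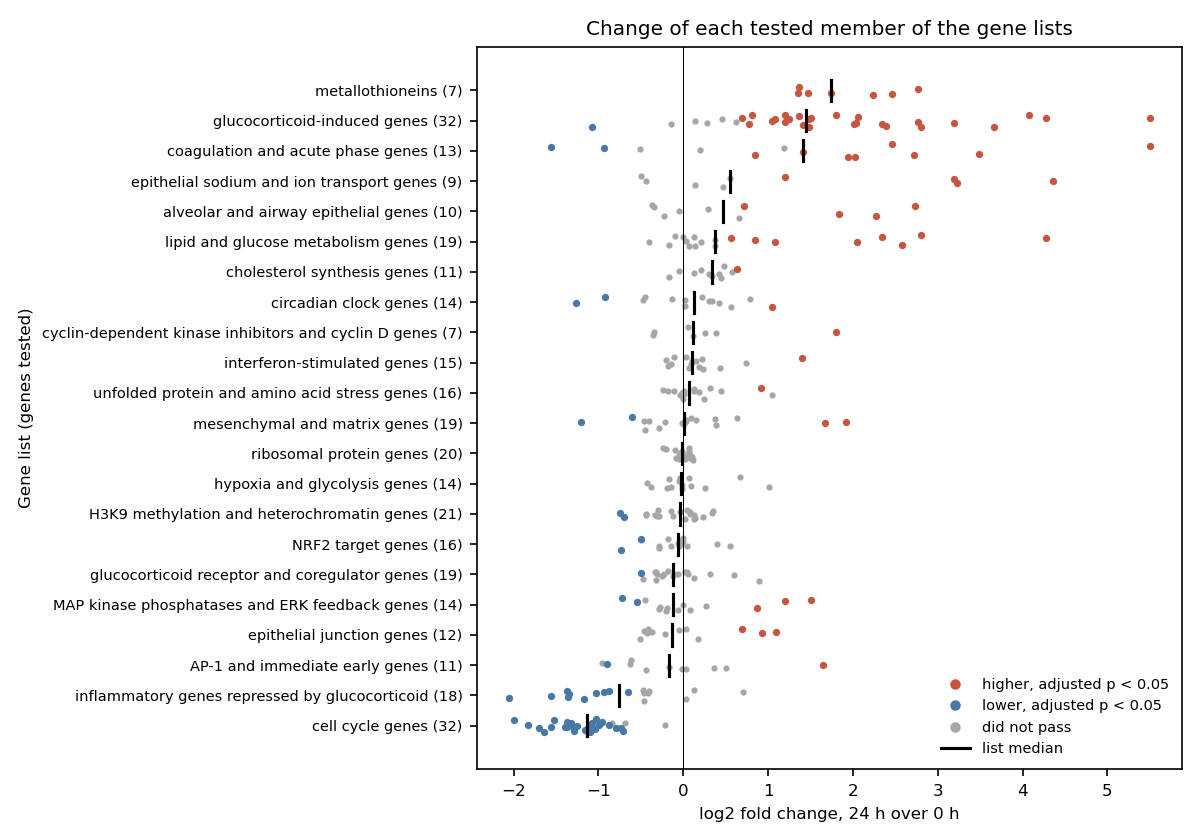
log2 fold change at 24 h over 0 h (x axis) of each tested member of the 22 gene lists (y axis, number tested in brackets). Red and blue points passed the limma test at an adjusted p of 0.05 as higher or lower, grey points did not, and black bars are list medians, which run from -1.14 for cell cycle genes to 1.74 for metallothioneins.

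Of 32 tested glucocorticoid-induced genes, 26 were higher and 1 was lower, with 27 and 1 adjusted over the list alone and 28 and 1 with the replicate block. Their median log2 change was 1.44, at 1.53 on slide 1 and 1.33 on slide 2 (camera adjusted p = 1.15e-27, and adjusted p = 0.000464 with an estimated correlation). TSC22D3, an anti-inflammatory leucine zipper protein, rose by 3.19 ± 0.25, ERRFI1, a feedback inhibitor of the EGF receptor, by 1.51 ± 0.15, and DUSP1, a MAP kinase phosphatase, by 1.20 ± 0.18 (SE). The 1 lower gene was CRISPLD2, although the list holds it as an induced gene. DEPP1, GLUL, SLC19A2, TIPARP and LCN2 did not pass, at -0.15, 0.14, 0.28, 0.45 and 0.62.

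All 7 tested metallothioneins, small proteins that bind zinc and copper, were higher, also adjusted over the list alone, with MT1X up by 2.77 ± 0.21 and MT1F by 1.74 ± 0.30. Their median change was 1.74, at 1.27 on slide 1 and 2.20 on slide 2 (camera adjusted p = 1.72e-08). The call was lost with an estimated correlation (adjusted p = 0.162).

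Of 13 coagulation and acute phase genes, 8 were higher and 2 lower, with 9 and 3 adjusted over the list alone and 8 and 3 with the replicate block. Complement C3, detected on 2 of 4 arrays at 0 h, rose by 1.95 ± 0.19, beside SERPINA3 and SAA1, and the higher genes included the fibrinogen chains FGA, FGB and FGG, of which a dimmer FGG probe did not pass. PLAT, the tissue plasminogen activator, was at least 1.98-fold lower and not detected at 24 h, and the other lower gene was PLAUR, the urokinase receptor. The list's median was 1.41, at 1.60 on slide 1 and 1.71 on slide 2 (camera adjusted p = 0.000165, and adjusted p = 0.168 with an estimated correlation).

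Of 9 epithelial sodium and ion transport genes, 4 were higher and none lower, with 5 higher and 1 lower adjusted over the list alone and the same numbers with the replicate block. The 4 were SCNN1G, SCNN1B, TSC22D3 and SGK1, a kinase that acts on the sodium channel, at 1.19 ± 0.16. TSC22D3 and SGK1 are also in the glucocorticoid-induced list. The median was 0.55, at 1.22 on slide 1 and 0.40 on slide 2 (camera adjusted p = 1.09e-05, and adjusted p = 0.0207 with an estimated correlation).

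Of 19 lipid and glucose metabolism genes, 8 were higher and none lower, with 9 and 1 adjusted over the list alone and 9 and 0 with the replicate block. ACSL1, a fatty acyl-CoA synthetase, rose by 2.58 ± 0.18, ANGPTL4, an inhibitor of lipoprotein lipase, by 2.80 ± 0.28, and PRODH, which degrades proline, by 2.05 ± 0.22. The median was 0.38, at 0.28 on slide 1 and 0.41 on slide 2 (camera adjusted p = 3.33e-06, and adjusted p = 0.0243 with an estimated correlation).

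Of 10 alveolar and airway epithelial genes, 4 were higher and none lower, with 4 and 1 adjusted over the list alone, and also with the replicate block. SFTPD, surfactant protein D, rose by 2.73 ± 0.19 and SLPI, a secreted protease inhibitor, by 2.27 ± 0.46. MUC1, a membrane mucin, rose by 1.84 ± 0.26 and ABCA3, a surfactant lipid transporter, by 0.72 ± 0.15. The median was 0.47, at 0.22 on slide 1 and 0.75 on slide 2 (camera adjusted p = 0.0231). The call was lost with the replicate block (adjusted p = 0.0769), with an estimated correlation (adjusted p = 0.411) and without 24 h replicate 4 (adjusted p = 0.0526).

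Of 11 cholesterol synthesis genes, 1 was higher, also adjusted over the list alone, and 2 with the replicate block. The 1 gene, LSS, which makes lanosterol, changed by 0.63 ± 0.16, its other tested probes did not pass, and its call ended on leaving out any of 6 of the 8 arrays (adjusted p = 0.0543 to 0.101). The median of the list was 0.34, at 0.16 on slide 1 and 0.35 on slide 2 (camera adjusted p = 0.0167). The call was lost with an estimated correlation (adjusted p = 0.221), on slide 1 alone (adjusted p = 0.259) and without 24 h replicate 4 (adjusted p = 0.0632).

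Of 32 tested cell cycle genes, 29 were lower and none higher, with 31 lower adjusted over the list alone and 30 with the replicate block. The log2 change was -1.33 ± 0.18 for MCM7, a subunit of the replicative helicase, -1.39 ± 0.20 for AURKB, a mitotic kinase, -1.37 ± 0.20 for TTK, a kinase of the spindle checkpoint, and -1.25 ± 0.18 for BIRC5, the apoptosis inhibitor survivin. The genes that did not pass were PCNA at -0.69, PLK1 at -0.22 and BUB1B at -0.84. Of the dimmer PCNA probes, 1 passed at -1.001 (adjusted p = 0.0272) and 1 did not, at -0.13. The median was -1.14, at -0.79 on slide 1 and -1.59 on slide 2 (camera adjusted p = 1.15e-23). The call was lost with an estimated correlation (adjusted p = 0.159).

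Of 18 tested inflammatory genes of the repressed list, 10 were lower and none higher, with 12 lower adjusted over the list alone, and 1 higher and 11 lower with the replicate block. RELB and NFKB2, subunits of NF-kappa-B, changed by -1.36 ± 0.16 and -1.37 ± 0.19, and CXCL5, a neutrophil chemokine, by -1.35 ± 0.16. CXCL8 differed by -0.46 ± 0.31 and did not pass (adjusted p = 0.443). The median was -0.76, at -0.77 on slide 1 and -0.83 on slide 2 (camera adjusted p = 3.57e-08, and adjusted p = 0.00904 with an estimated correlation).

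**Figure D3:**
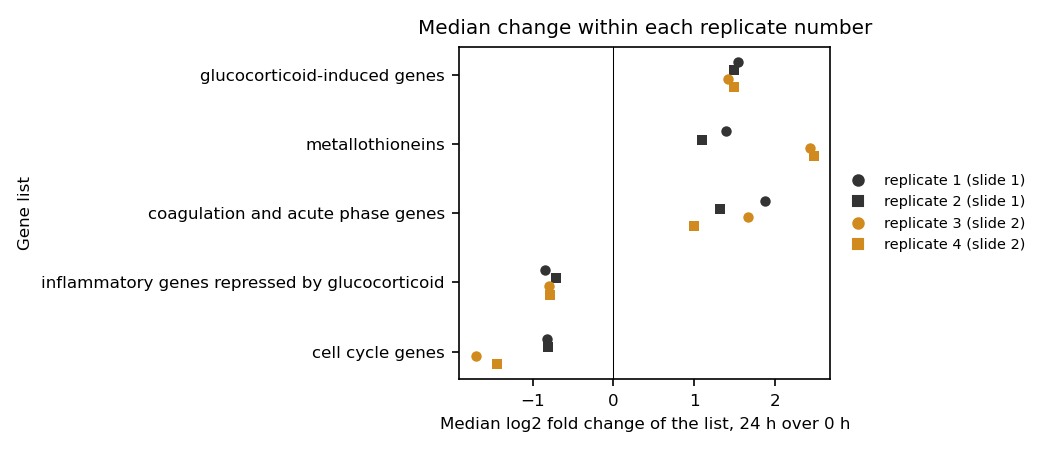
Median log2 fold change of 5 gene lists at 24 h over 0 h (x axis) within each replicate number, with slide 1 in black and slide 2 in orange. Cell cycle genes lie at -0.82 and -0.80 in replicates 1 and 2 and at -1.70 and -1.44 in replicates 3 and 4, while glucocorticoid-induced genes lie between 1.42 and 1.54 in all 4.

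The other 13 lists did not pass camera. Among 7 cyclin-dependent kinase inhibitors and cyclin D genes, CDKN1C, the inhibitor p57, was the 1 gene called and rose by 1.81 ± 0.25 (list adjusted p = 0.391). Among 11 AP-1 and immediate early genes, FOS rose by 1.65 ± 0.15 and ATF3 fell by 0.90 ± 0.18 (list adjusted p = 0.546). Of 14 MAP kinase phosphatase and ERK feedback genes, ERRFI1, DUSP1 and SPRY1 rose and PHLDA1 and ETV4 fell (list adjusted p = 0.988), though a dimmer ETV4 probe did not pass. Of 14 circadian clock genes, PER1, detected on only 1 of 4 arrays at 0 h, so that its rise is measured from about background, rose by 1.05 ± 0.23, NR1D2 changed by -1.26 ± 0.18 and CRY1 by -0.92 ± 0.21 (list adjusted p = 0.938), and CRY1 lost its call without 0 h replicate 2, 24 h replicate 3 or 24 h replicate 4 (adjusted p = 0.0517 to 0.0595). Of 15 interferon-stimulated genes, IFIT1 rose by 1.40 ± 0.31 (list adjusted p = 0.207), and of 16 unfolded protein and amino acid stress genes, CEBPB rose by 0.91 ± 0.18 (list adjusted p = 0.291).

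Of 12 epithelial junction genes, 3 were higher (list adjusted p = 0.992). They were KRT8 at 0.93 ± 0.19, CDH1, the cell adhesion protein E-cadherin, at 1.09 ± 0.24 and KRT18 at 0.69 ± 0.18. CDH1 lost its call without 0 h replicate 2 (adjusted p = 0.0501), and KRT18 on leaving out any of 5 of the 8 arrays (adjusted p = 0.0861 to 0.105). A dimmer KRT18 probe differed by 0.32 and did not pass (adjusted p = 0.361). Of 19 mesenchymal and matrix genes, LOX, which cross-links collagen, rose at least 2.51-fold and SNAI2, a transcription factor, by 1.67 ± 0.33 (list adjusted p = 0.938). COL4A1 at -0.61 ± 0.15 and COL1A1 at -1.21 ± 0.32 were called lower, and lost the call on leaving out any of 6 and any of 7 of the 8 arrays (adjusted p = 0.0584 to 0.0905 and 0.054 to 0.0917).

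Of 21 H3K9 methylation and heterochromatin genes, DNMT1, the maintenance DNA methyltransferase, changed by -0.74 ± 0.16 and CBX5, the heterochromatin protein HP1 alpha, by -0.70 ± 0.16 (list adjusted p = 0.323). CBX5 lost its call without 24 h replicate 4 (adjusted p = 0.0512). Of 19 glucocorticoid receptor and coregulator genes, the chaperone HSP90AB1 was called lower at -0.50 ± 0.13 and lost the call on leaving out any of 6 of the 8 arrays (adjusted p = 0.0739 to 0.115, list adjusted p = 0.358). Of 16 NRF2 target genes, SLC7A11, a cystine transporter, fell by 0.74 ± 0.15, and SRXN1 at -0.50 ± 0.13 was called but not on leaving out any of 6 of the 8 arrays (adjusted p = 0.0563 to 0.0959, list adjusted p = 0.323). Limma called none of 14 hypoxia and glycolysis genes, with 4 at an unadjusted p under 0.05, and none of 20 ribosomal protein genes, with 0 at that level. Their list adjusted p was 0.992 each. Adjusted over the list alone, HSP90AB1 lost its call, leaving 0 higher and 0 lower in the receptor list, and higher and lower members were 1 and 3 for AP-1, 3 and 3 for MAP kinase feedback, 3 and 4 for the clock, 1 and 2 for the NRF2 list and 2 and 0 for the interferon and for the stress genes, with the other lists unchanged. With the replicate block, more members of 12 of these 13 lists were called. Higher and lower members were 2 and 1 for the kinase inhibitors and cyclin D, 1 and 2 for AP-1, 3 and 3 for MAP kinase feedback, 3 and 4 for the clock, 2 and 0 for the interferon and for the stress genes, 3 and 2 for the junction, 4 and 4 for the mesenchymal, 0 and 3 for the H3K9, 1 and 1 for the receptor, 1 and 2 for the NRF2 and 2 and 1 for the hypoxia list. Among named genes not called in the main fit, the block called NDRG1 (1.01), P4HA1 (0.66), IRF9 (0.74), PGD (0.40), CALCOCO1 (0.59), DDIT4 (1.04) and CDKN1B (0.39) higher. It called MARVELD2 (-0.43), PFKFB3 (-0.38), CBX1 (-0.44), CCND3 (-0.34) and NPAS2 (-0.45) lower. For these genes, limma adjusted p with the block ran from 0.00698 (NDRG1) to 0.0495 (NPAS2). MARVELD2 was detected on 3 of 4 arrays at 0 h and 2 of 4 at 24 h. CDKN1C, SNAI2 and PRODH were detected on 3 of 4 at 0 h.

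Median and camera direction had opposite signs for the MAP kinase feedback, junction and hypoxia lists, and fry had the opposite direction to camera for the clock list.

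No set test was run on the markers of other cell types. Of 6 tested fibroblast markers, DCN, a matrix proteoglycan, rose at least 2.92-fold and COL1A1 was lower. Limma called none of 4 leukocyte markers, with 1 at an unadjusted p under 0.05, 1 lower adjusted over the list alone and 3 negative estimates, and none of 4 endothelial markers, with 0 and 4 negative estimates. Of 10 markers of the A549 line, CPS1, the urea cycle enzyme, rose by 1.06 ± 0.20, beside KRT8 and KRT18, with 4 higher adjusted over the list alone.

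Within slide 1, with 2 arrays at each time, limma called 263 genes higher and 293 lower, and within slide 2 it called 188 and 171, while the slide as a block gave 736 and 793. The 0 h and 24 h arrays alternate along each slide and share no position.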

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

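The tests of other splits of the arrays, of array position, of pairing and of scaling were chosen after the result they bear on had been seen.

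In 20 of 240 groups of 4 arrays (8.33%, where chance gives about 1 in 20), 1 array lay far from the other 3, judged by its gap as a share of the group's whole range. At 0 h, replicate 3 stood highest for ATF3 (share 0.984), MAOA (0.844), MARVELD2 (0.861), DCN (0.848) and CDH1 (0.83), and lowest for MCM10 (0.886). At 0 h, replicate 4 stood highest for CPA4 (0.953, log2 10.1 against 8.30 to 8.39) and lowest for PRODH (0.984), XBP1 (0.874), TSC22D3 (0.857, log2 9.87 against 10.9 to 11.1), MT1H (0.853) and FBLN1 (0.838). At 0 h, replicate 1 stood highest for ZBTB16 (0.926), undetected there, and for CDKN2B (0.838). At 24 h, replicate 3 stood highest for COL1A1 (0.922), MUC1 (0.859) and SERPINA3 (0.831), replicate 2 stood lowest for JUN (0.885) and highest for SOX2 (0.864), and replicate 4 stood highest for CDH1 (0.855).

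Of 1607 tested rows outside the authors' normalized table, 106 passed the limma test between 0 h and 24 h, 46 higher and 60 lower. They carry no gene name here.

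The number of called genes, 1113, was not met by any other of the 35 splits of the 8 arrays into 4 and 4 (1 of 35 as large, the real one included). The highest other split, which follows the slides, called 12. For genes changed at least 1.5-fold the real count was 961 and the highest other 12 (again 1 of 35). Most of these 35 splits ignore the pairing, so this share cannot exclude chance for either count. Only 8 splits part all 4 replicate pairs as the real one does, too few for a share under 0.05 (the smallest is 0.125). Among the other 7 of these, limma called at most 0 genes, with at most 352 at an unadjusted p under 0.05, against 1113 and 2516 for the real split. Every other split puts arrays of both times on each side, so a difference between the times widens its spread and lowers its gene counts. Those counts are therefore no fair measure of what chance gives. For gene lists the real split called 9 and the highest other 10, and 4 of 35 splits called as many, so the splits do not exclude chance for the number of lists called by camera with its preset correlation. The 3 others each have 3 arrays of one time on one side and so carry part of the contrast between the times, while the 18 splits with 2 arrays of each time on each side called at most 3 lists.

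The fall of the cell cycle genes was set against scaling between arrays and array position. With each array only scaled to 1 median, the median change of the 32 cell cycle genes minus that of all probes was -1.145. It was -1.13 with the authors' values, whose normalization steps are not known, so these do not bear on quantile normalization. With quantile normalization it was -1.132, so the median-scaled value argues against that step as the cause. A factor common to all probes of an array cancels in the cell cycle median minus that of all probes. The choice of such a factor could therefore not have moved it. A gradient along the slide is argued against as well. The times alternate along each slide, and from the second array (24 h) to the third (0 h) the median of the cell cycle genes rose by 0.8085 on slide 1 (31 of 32 members higher) and by 1.87 on slide 2 (32 of 32), where a gradient that lowers the second array would lower the third too. The number of slide positions used for both times was 0, so an effect of position other than a gradient cannot be told apart from that of time. The response to hormone stays open as well, untested here. No array of cells kept 24 h without dexamethasone was analysed, so time in culture cannot be told apart from the hormone.

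Arrays with the same replicate number deviated together. Within each slide, the difference between its 2 replicate numbers at 0 h correlated across probes with that at 24 h, at r = 0.468 and 0.387 (lower value 0.3867), which argues against the slide as the only cause, since both numbers share it. Array brightness stays open, because dim minus bright differences correlated between the slides at 0.1739, too weakly to account for the pairing and too strongly to be set aside. Genes are not independent replicates in these correlations. Separate cultures would also pair the arrays, which the labels neither state nor exclude, and no biological explanation was tested. Same-numbered arrays also follow each other among the analysed positions of their slide, though not at adjoining letters. An effect of place within a slide could therefore pair them too and stays open.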

How the results depend on the processing

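Of the 25 alternatives, 2 (the background from the negative control rows, and the added rows outside the authors' table) were chosen after seeing the data. No called list changed direction, and none of the 1113 called genes did where it was tested (986 of them with probes detected on all arrays, 1089 with the stricter detection p, all elsewhere). The replicate block moved the counts from 522 and 591 to 888 higher and 1002 lower and ended the call of the alveolar and airway list (adjusted p = 0.0769), and no other list gained or lost its camera call. It kept 1105 of the 1113 genes and added calls for 12 of 117 named genes. Within slide 1 the counts were 263 higher and 293 lower, all at least 1.5-fold, and within slide 2 they were 188 and 171, likewise, with 461 and 323 of the 1113 genes called. Fewer arrays were fitted there. The cholesterol list was lost on slide 1 (adjusted p = 0.259) and the interferon list passed on slide 2 (adjusted p = 0.0118). With an estimated correlation the lists lost were metallothioneins (0.162), cell cycle (0.159), alveolar (0.411), cholesterol (0.221) and coagulation (0.168), all adjusted p, and with fry the H3K9 list passed (0.0164). Fry asks a different question, and for the others the cause was not tested. Leaving out 1 array at a time, the adjusted p of the alveolar list ran from 0.00782 to 0.0526 and that of the cholesterol list from 0.00544 to 0.0632, both lost without 24 h replicate 4, and called genes ran from 772 (without 24 h replicate 3) to 1026. In the other settings called genes ran from 991 with median scaling, which kept 954 of the 1113, to 1529 with a slide block, and the authors' values gave 1175, which kept 1087. In all, 82 of 92 counts stayed within 1.5 times, and 511 of 550 list results and 2497 of 2664 named gene results kept direction and side, with 28 and 12 of opposite direction, 98 named gene results weaker, 37 of them within slide 2, and 57 stronger. Directions changed for 6 lists and 8 genes that passed in neither setting, and the cause was not tested. The junction list turned down with median scaling (adjusted p = 0.913), the mean over probes (0.966, like hypoxia), the replicate (0.889) and slide block (0.945) and on slide 2 (0.911), MAP kinase feedback with the replicate block (0.947) and on slide 1 (0.887, like the clock), mesenchymal on slide 2 (0.927) and with probes detected on all arrays (0.578), and the clock there (0.600) and with fry (0.858). Ribosomal genes turned up there (0.971) and without a filter (0.989). Some omissions of 1 array turned these lists too, except the clock. Over all 8 omissions, whether they turned it or not, adjusted p ran from 0.842 to 0.994 (junction), 0.684 to 0.994 (MAP kinase feedback), 0.355 to 0.994 (mesenchymal) and 0.838 to 0.998 (hypoxia and ribosomal). Of genes, the mean over probes gave HSP90AA1 0.0617 and NR3C1 0.0709, slide 2 gave RPS2 -0.000468, PDGFRA 0.0156, MS4A1 0.00261, CD68 -0.0465 and TIE1 0.0642, and over all 8 omissions CD68 ran from -0.0680 to 0.3, PECAM1 from -0.208 to 0.0546 and NR3C1 from -0.143 to 0.0166. The median change of all probes lay between -0.023 and -0.0027 in all settings. Signal over background limits dim genes such as EHMT1, since the array median was only 1.62 to 2.28 times that of the negative controls.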

Other observations

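The gene lists described here and the comparison of the slides were chosen after the data had been seen, and the split of cell cycle genes by phase was set up after the falling genes were known but before its values were computed. For the slides, the test on glucocorticoid-induced genes was set after their values were seen and the test on risen genes before.

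These lists were made with the changed genes in view, so no list test is given for them, and the genes given values are called members picked outside the rule for named genes. Of 16 tested genes of homologous recombination and the Fanconi pathway, which repair DNA breaks and cross-links, limma called 12 lower and none higher at 24 h, and 4 did not pass. Their median log2 change was -1.22. BLM, a helicase, changed by -1.73 ± 0.19 (SE), RAD51AP1 by -1.61 ± 0.20, FANCI by -1.40 ± 0.17 and BRCA1 by -1.28 ± 0.19. None of the 16 is in the lists fixed before, but RAD51AP1, BLM and EXO1 are also among the G1/S genes.

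Of 15 tested genes of prostaglandin and leukotriene handling, 5 rose, 1 fell and 9 did not pass, with a median of 0.01. The prostaglandin receptors PTGER4 and PTGER2 rose by 1.65 ± 0.14 and 1.41 ± 0.31, the phospholipase PLA2G10 by 1.61 ± 0.25 and HPGD, which degrades prostaglandins, by 1.36 ± 0.19, beside ALOX5AP. TBXAS1, thromboxane synthase, fell by 0.85 ± 0.19. Among 15 negative regulators of inflammatory signalling, IRAK3, detected on 2 of 4 arrays at 0 h, rose by 2.28 ± 0.16, ZFP36, which destabilises cytokine mRNA, by 1.69 ± 0.16 and ZC3H12A, an RNase, by 1.52 ± 0.23, while SOCS2 fell by 1.03 ± 0.15. Of this list, 3 were higher and 1 lower.

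A hypothesis was that G1/S genes fall further than G2/M genes, as an arrest before S phase could give. Of 37 G1/S genes 29 were lower, and of 47 G2/M genes 38. The G1/S median minus the G2/M median was -0.17, -0.18, 0.09 and -0.09 in replicates 1 to 4, with a mean of -0.0884, so the predicted difference of 0.2 in each was not met.

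Cell cycle genes fell further on slide 2 than on slide 1, with medians of -1.59 and -0.79, and 31 of 32 members changed more on slide 2. Relative to each gene's mean, their median level at 0 h was 0.78 on slide 2 and 0.47 on slide 1, and at 24 h -0.74 and -0.37. The difference itself passed camera with the preset correlation (adjusted p = 2.48e-16) but not with an estimated one (adjusted p = 0.972, the value of every list). Limma called 0 genes for it. Of 10964 genes, 1746 had an unadjusted p under 0.05, more than the 0.05 share that chance gives on average. The difference is therefore neither established nor excluded. Fold changes compressed at every level on slide 1, the dimmer slide, are argued against by the glucocorticoid-induced genes, whose median change on slide 2 was 0.8685 times that on slide 1, with 1.42 to 1.54 in the 4 replicates. Metallothioneins went with such compression instead, with a median change 1.73 times as large on slide 2 and 7 of 7 members larger there. Their difference passed camera with the preset correlation (adjusted p = 4.1e-05) but not with an estimated one (adjusted p = 0.972). Compression at the brightness of the cell cycle genes stays open, since 217 risen genes of that level had a ratio of 1.251, between the bounds set for and against it, and a difference between cultures may also contribute and was not tested.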
